A study of Mus musculus with 18 samples.

How the data were processed

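The series measured polyadenylated RNA in brain cortex of adult mice of 3 genotypes, with 6 libraries each, 3 from males and 3 from females. WT animals were C57BL/6J. Dp16 animals carry a segmental duplication of mouse chromosome 16 that is used to model trisomy 21, so that genes of the segment are present in 3 copies in place of 2. In Dp16_2xIFNRs animals the cluster of interferon receptor genes inside the segment is back at 2 copies while the rest of the duplication remains. Groups, sex and age were taken from the labels, in which age ran from 17.1 to 18 weeks. Each library is labelled as a separate sample of its group, and p-values of single genes and of scores measure the spread between these samples.

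Per the labels' protocols, RNA was extracted with TRIzol, selected for polyadenylated RNA, made into strand-specific libraries with a Tecan/Nugen Universal Plus mRNA kit and sequenced from both ends on an Illumina NovaSeq instrument. Per the submitters' processing notes, bcl2fastq, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.5 and HTSeq 0.6.1 were used with the genome build GRCm38, and the deposited tables carry the gene set of GENCODE release M24. The strand setting of the counting, the treatment of reads that match several genes and any filter are not given in the sources used here. Values of overlapping or antisense genes and of near-identical copies, such as histocompatibility, immunoglobulin and histone genes, are therefore uncertain.

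The authors deposited raw counts per gene, 1 value per gene and library, without normalization. The authors also deposited RPKM values, and for 31735 of 31735 genes with counts in 2 or more libraries these equalled the count divided by the library total and by a single length per gene, within a relative tolerance of 1e-06. RPKM values entered only an alternative fit. Library totals ran from 46346019 to 67281449 counts. At this depth the common biological coefficient of variation was 12.2% and the residual degrees of freedom numbered 14. Intervals computed from counts cover counting error only.

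Of 55385 genes in the count table, 55144 were placed by identifier in GENCODE release M21 of the same build, and positions are given from that release. The segment was taken from Lipi to Zbtb21, at positions 75540514 to 97962622 of chromosome 16. Ifnar1, Ifnar2, Ifngr2 and Il10rb made up the receptor cluster. Counts were filtered with filterByExpr by group (edgeR 4.0.16, minimum count 10), which left 18717 genes, 115 in the segment and 18602 outside. Counts were normalized by TMM and tested with edgeR's quasi-likelihood F test with robust dispersions, with genotype and sex as terms and all 18 libraries in the fit, in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Adjusted p-values of single genes come from this test unless another tool is named. Log2 fold changes are given with the standard error (SE), and CPM as mean ± SD over 6 libraries.

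For gene lists, the mean over members of the log2 CPM (prior count 2) less the WT mean gave a score per library, and for the segment and the receptor cluster the median was used. Scores were compared by two-sided exact permutation tests over the 924 arrangements of 12 libraries, whose smallest possible p is 0.00216, with 95% intervals from the same test and no adjustment over lists. Score tests without WT replicate 6 were chosen after seeing the data. List tests used camera (limma 3.58.1) on voom values with a preset correlation between genes of 0.01, adjusted over the 45 lists with 3 or more tested members in each contrast. They were repeated with an estimated correlation and with fry. With the preset correlation, camera's p compares genes inside and outside a list and does not measure the spread between samples. The estimated correlation in Dp16 vs WT was 0.221 for the type I interferon-stimulated, 0.659 for the microglia and 0.849 for the ribosomal protein list. Members inside the segment were left out of all lists except those of the segment itself. The lists covered interferon and immune genes, glia, neurons, vessels, neighbouring tissues, stress, metabolism and synapses.

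The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named were the 4 receptor genes, in the segment the 10 genes of smallest p and up to 6 well-expressed genes of lowest fold change in Dp16 vs WT plus 16 fixed names, outside the segment the 10 called genes of largest and the 10 of smallest log2 fold change that carry a proper gene name, up to 4 called members per list, and the leading genes for sex and its interaction. Where a list had no called member, up to 2 members are given as values.

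Alternatives covered size factors by the RLE method, TMM from genes outside the segment, DESeq2 1.42.0, limma-voom with and without sample quality weights, no filter, a filter of at least 1 CPM in 6 libraries, models without sex or with age or sample identifiers, a replicate block, only the 12 libraries compared, a single sex, limma on log2(RPKM + 0.1), thresholds of 0.01 and 0.1, and leaving out each library. A fit with choroid plexus and striatum scores as covariates, and a fit without WT replicate 6 and Dp16 replicate 3, were chosen after seeing the data. No pair of libraries of the same genotype agreed within sampling noise.

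The tests were run on simulated counts of the 18717 genes, with 200 genes changed. For Dp16 vs WT, edgeR recovered 67.2% of genes changed 1.5-fold, 86.6% at 2-fold and 95.5% at 4-fold, with 15 false calls among 181. For Dp16_2xIFNRs vs WT it recovered 62.7%, 89.6% and 98.5%, with 4 false calls among 171, and for Dp16_2xIFNRs vs Dp16 62.7%, 80.6% and 93.9%, with 8 among 166. For the interaction of sex with Dp16 vs WT it recovered 29.9%, 52.2% and 84.8%.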

Results

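Cortex transcriptomes of 18 adult mice were compared, 6 WT, 6 Dp16 and 6 Dp16_2xIFNRs. The totals per library ran from 47554526 to 52006799 counts in WT, from 46346019 to 67281449 in Dp16 and from 47912340 to 61150849 in Dp16_2xIFNRs (n = 6 each). The comparison of Dp16 with WT asks what the duplication changes, that of Dp16_2xIFNRs with WT what changes when the receptor genes are at the normal copy number, and that of both duplication genotypes what the additional copy of the receptor genes changes.

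In Dp16 cortex, genes of the duplicated segment rose together by a factor close to the copy ratio of 1.5. App, which encodes the amyloid precursor protein, rose from 1890 ± 130 to 2780 ± 226 CPM. Sod1, a superoxide dismutase, rose from 182 ± 12.6 to 257 ± 14.3 CPM, and the kinase gene Dyrk1a from 92.4 ± 4.68 to 131 ± 8.33 CPM (SD, n = 6). Across the 111 tested segment genes outside the receptor cluster, the median fold change was 1.46, 109 were above WT, 64 were called higher and none lower, and 81 lay between 1.3-fold and 1.7-fold. Adjusted over the list alone, 88 were higher and 0 lower. The median per library was 0.56 ± 0.018 on the log2 scale in Dp16 and 0.00 ± 0.009 in WT, a difference of 0.56 (95% interval 0.54 to 0.58, exact permutation p = 0.00216, the smallest possible).

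The smallest p-values in the segment belonged to Cryzl1 (log2 fold change 0.60, SE 0.0347, adjusted p = 2.06e-09), Wrb (0.64, SE 0.0414, adjusted p = 1.14e-08), the calcineurin inhibitor Rcan1 (0.63, SE 0.0425, adjusted p = 1.82e-08) and Gart of purine synthesis (0.57, SE 0.0393, adjusted p = 1.82e-08). Cct8, Atp5j, Tmem50b, Vps26c, Hspa13 and Dnajc28 followed, with folds of 1.53, 1.51, 1.5, 1.52, 1.49 and 1.57. Called higher as well were Itsn1 (1.39-fold), Synj1 (1.49-fold), Son (1.42), Ets2 (1.42), Hmgn1 (1.5), Bach1 (1.35), Usp16 (1.41) and the potassium channel gene Kcnj6 (1.46). Among well-expressed genes the lowest values were those of Erg (fold 1.12, adjusted p = 0.683), Hunk (1.12, adjusted p = 0.933), Prdm15 (1.21, adjusted p = 0.455), Olig2 (1.26, adjusted p = 0.287) and Slc5a3 (1.28, adjusted p = 0.238). Olig1, a transcription factor of oligodendrocytes, was called at 1.28-fold (adjusted p = 0.0371). Mx1 (2.75-fold, adjusted p = 0.088) and Runx1 (1.41-fold, adjusted p = 0.243) were not called. The call of Olig1 ended when any of 11 libraries was left out, with an adjusted p of up to 0.0954 without WT replicate 3. Those of Usp16 (7 libraries, up to 0.0993 without Dp16 replicate 5) and Kcnj6 (0.0512 without Dp16 replicate 5) ended too.

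**Figure D1:**
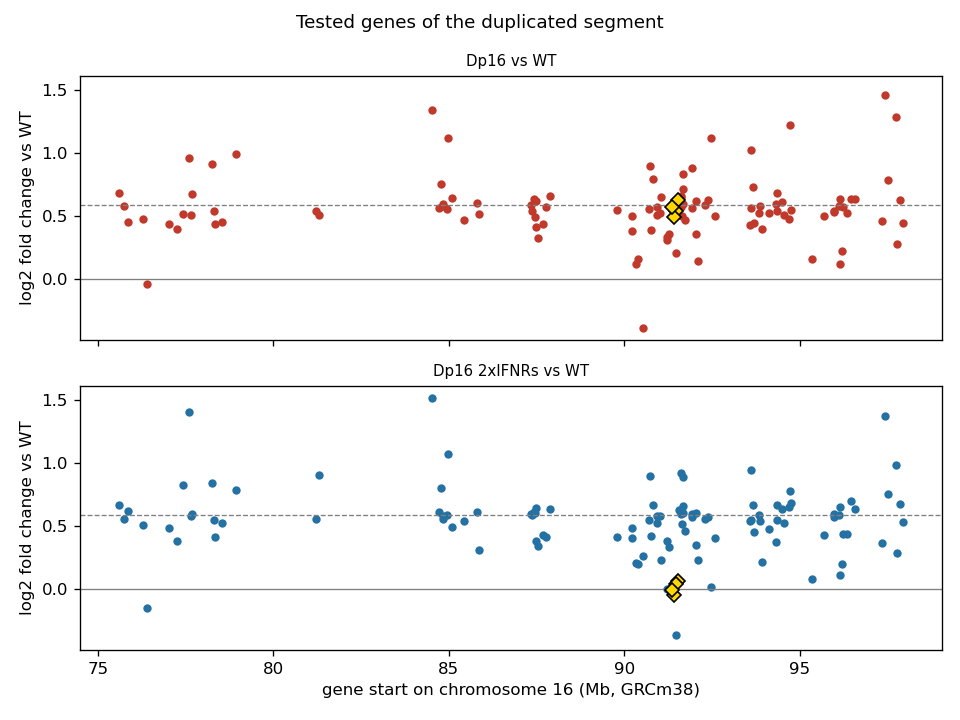
Log2 fold change against WT of the 115 tested genes of the duplicated segment (y axis) by gene start on chromosome 16 in Mb (x axis), for Dp16 (upper panel) and Dp16_2xIFNRs (lower panel). Circles are single genes, diamonds are the 4 receptor genes, the solid line marks 0 and the dashed line the log2 of the copy ratio 1.5, 0.585. The receptor genes lie with the rest of the segment in Dp16 and near 0 in Dp16_2xIFNRs.

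The 4 receptor genes rose with the rest of the segment in Dp16. Ifnar1 and Ifnar2 encode the receptor for type I interferons, Ifngr2 a chain of the receptor for interferon gamma and Il10rb a chain shared by receptors of the interleukin 10 family. Ifngr2 rose from 40 ± 1.63 to 61.9 ± 2.72 CPM (log2 fold change 0.63, SE 0.0493, adjusted p = 8.33e-08) and Ifnar1 from 44.3 ± 3.46 to 64.6 ± 1.5 CPM (0.54, SE 0.0447, adjusted p = 1.77e-07). Ifnar2 rose from 14.8 ± 1.51 to 21.9 ± 1.06 CPM (0.57, SE 0.0629, adjusted p = 1.01e-05), and Il10rb from 6.72 ± 0.770 to 9.49 ± 1.16 CPM (0.50, SE 0.0869, adjusted p = 0.00386). Ifnar2 starts at position 91372783 and Ifngr2 ends at 91565623 of chromosome 16. The 12 listed neighbours of the cluster all lay above WT, with a median of 0.57 on the log2 scale and 10 called.

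Outside the segment, 51 genes rose and 21 fell in Dp16. The largest change in both duplication genotypes was that of the nonagouti gene, symbol a, on chromosome 2 from 154791402 to 155051012. It encodes the agouti signalling protein, known for its role in coat colour. WT libraries held 6 counts of it in all and at most 2 in any, whereas Dp16 libraries held 59 to 86 counts and Dp16_2xIFNRs libraries 57 to 103. The level was 0.0204 ± 0.0184 CPM in WT, 1.36 ± 0.123 in Dp16 (adjusted p = 1.56e-09) and 1.37 ± 0.313 in Dp16_2xIFNRs (adjusted p = 1.45e-09). Pooled over libraries, the duplication genotypes stood 67.9-fold above WT, with a 95% counting interval of 31.1 to 186.

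**Figure D2:**
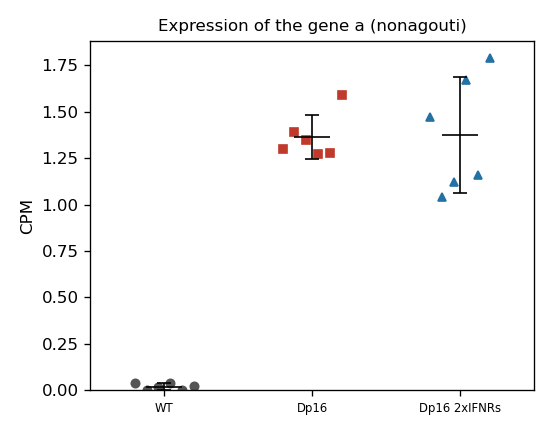
CPM of the nonagouti gene (y axis, from 0) in each library of the 3 genotypes (x axis). Points are single libraries and bars give the mean and SD of 6 libraries. All 12 duplication libraries stand above all 6 WT libraries, at means of 1.36 and 1.37 CPM against 0.0204.

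Sycp3 of the synaptonemal complex rose 4.05-fold to 0.526 ± 0.172 CPM (adjusted p = 0.00153), Selenov 3.00-fold to 1.47 ± 0.425 CPM (adjusted p = 2.78e-05) and Rnf17 2.18-fold to 1.29 ± 0.284 CPM (adjusted p = 0.00565). Bst1 rose 2.64-fold (adjusted p = 0.00907), Siglec1 2.58-fold (adjusted p = 0.027), Lgals3 2.43-fold (adjusted p = 0.0398) and Folr2 2.18-fold (adjusted p = 0.0386). Cd300lg (5.12-fold, adjusted p = 0.028) and the siderophore-binding Lcn2 (4.29-fold, adjusted p = 0.0398) completed the largest changes. Removal of single libraries ended some of these calls, with adjusted p of up to 0.141 for Lcn2 without Dp16 replicate 4, 0.0871 for Cd300lg without WT replicate 3, 0.0885 for Siglec1 without WT replicate 2, 0.104 for Lgals3 without WT replicate 2 and 0.108 for Folr2 without WT replicate 3.

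The transcription factor gene Tbx1, which lies on chromosome 16 outside the segment from 18580979 to 18590671, fell from 1.87 ± 0.274 to 0.534 ± 0.241 CPM in Dp16 (log2 fold change -1.80, SE 0.295, adjusted p = 0.00198). Gli1, a target of hedgehog signalling, fell to 0.537-fold (adjusted p = 0.00175) and Rec8, a meiotic cohesin, to 0.482-fold (adjusted p = 0.014). Cbs, the cystathionine beta-synthase gene on chromosome 17, fell from 31.5 ± 2.82 to 21.4 ± 2.53 CPM (adjusted p = 0.00212), and the citrate transporter gene Slc13a5 from 19 ± 2.16 to 13.7 ± 1.71 CPM (adjusted p = 0.00198). Snora65 (0.534-fold), Cyp11a1 (0.608), Tspan11 (0.731), Fbxo32 (0.740) and Kcnab3 (0.748) fell as well. Their calls ended without single libraries, at adjusted p of up to 0.0611 for Snora65 without WT replicate 5, and without WT replicate 2 of up to 0.113 for Cyp11a1, 0.0885 for Tspan11, 0.135 for Fbxo32 and 0.0574 for Kcnab3. The count of 72 outside genes fell to 38 without WT replicate 2 and to 41 without Dp16 replicate 4, and to 44 without both WT replicate 6 and Dp16 replicate 3.

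Interferon-stimulated genes rose as a group in Dp16 cortex. Of 46 tested members of the type I list, 44 lay above WT with a median log2 fold change of 0.25, and 3 were called, or 9 adjusted over the list alone. Lgals3bp rose 1.60-fold (adjusted p = 0.00181), Ifi27 1.3-fold (adjusted p = 0.00597) and Bst2 1.46-fold (adjusted p = 0.0492). The list was called by camera (adjusted p = 1.51e-13), with an adjusted p = 0.157 with an estimated correlation. Its score was 0.28 above WT (95% interval 0.09 to 0.49, exact permutation p = 0.0108), and 6 of 6 Dp16 libraries lay above the WT mean. The groups overlapped, with WT replicate 4 at 0.275 and Dp16 libraries from 0.129 to 0.439. In the interferon gamma and antigen presentation list, 29 of 33 members lay above WT, 3 were called and 9 were called adjusted over the list alone (adjusted p = 1.32e-10, and adjusted p = 0.306 with an estimated correlation), and its score was 0.303 above WT (95% interval 0.043 to 0.574, exact permutation p = 0.0238). Without WT replicate 6 that difference was 0.201 (95% interval 0.007 to 0.369, exact permutation p = 0.0455). The class I genes H2-D1 (1.29-fold, adjusted p = 0.0131) and H2-K1 (1.36-fold, adjusted p = 0.0409) and the class II loading gene H2-DMa (log2 fold change 0.32, adjusted p = 0.0249) rose. Without single libraries the adjusted p reached 0.134 for Bst2 (WT replicate 3), 0.12 for H2-K1 (Dp16 replicate 4) and 0.0774 for H2-DMa (Dp16 replicate 5). With the replicate block the calls of H2-D1, H2-K1, H2-DMa and Bst2 ended. The microglia score differed from WT by -0.08 (95% interval -0.26 to 0.16, exact permutation p = 0.504), and WT replicate 6 stood at -0.44 in it. Without that library the difference was -0.164 (95% interval -0.281 to -0.05, exact permutation p = 0.0216). The white blood cell score was 0.278 above WT (95% interval -0.059 to 0.62, exact permutation p = 0.104), close to the 0.28 of the type I list. Of the 24 genes in the white blood cell list 11 were tested. That list includes the macrophage genes Cd163, Mrc1 and Lyve1, so it is not specific to blood cells.

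Camera called reactive astrocyte genes higher, with 15 of 17 members above WT (adjusted p = 0.000459, and adjusted p = 0.365 with an estimated correlation), and 1 was called, or 4 adjusted over the list alone. The called member was Lcn2, whose call ended without any of 12 libraries. Lcn2 was also the only called member of the list of cytokines and NF-kB targets. Among genes of GABAergic neurons, 18 of 22 lay above WT (adjusted p = 0.00772, and adjusted p = 0.283 with an estimated correlation), and the neuropeptide gene Cort rose 1.73-fold (adjusted p = 0.000306), its own list holding 1 call and 2 adjusted over the list alone. The activated microglia gene Lyz2 rose 1.52-fold (adjusted p = 0.0015). Complement genes (13 of 15 above WT, adjusted p = 0.0241, and adjusted p = 0.671 with an estimated correlation), cilia genes (11 of 13, adjusted p = 0.0411, and adjusted p = 0.695 with an estimated correlation) and erythroid genes (6 of 8, adjusted p = 0.0426, and adjusted p = 0.695 with an estimated correlation) were also called higher, each without a called member. Cytosolic ribosomal protein genes were called lower by a small amount, with 1 of 38 above WT and a median of -0.10 (adjusted p = 6.85e-08, and adjusted p = 0.695 with an estimated correlation). Potassium channel genes (4 of 23 above WT, adjusted p = 0.00085, and adjusted p = 0.365 with an estimated correlation), proliferation genes (4 of 19, adjusted p = 0.0155, and adjusted p = 0.283 with an estimated correlation) and glutamate receptor genes (3 of 26, adjusted p = 0.0426, and adjusted p = 0.545 with an estimated correlation) were called lower as well, and none of these 4 lists held a called member. Adjusted over the list alone, 2 proliferation genes were lower and 2 complement genes higher. Compared between libraries, the score of reactive astrocyte genes was 0.312 above WT (95% interval 0.046 to 0.594, exact permutation p = 0.026, and 0.0584 without WT replicate 6) and that of GABAergic genes 0.101 (95% interval 0.021 to 0.172, exact permutation p = 0.0238). The other score intervals included 0, with exact permutation p of 0.0866 for complement, 0.206 for cilia, 0.0779 for erythroid, 0.223 for ribosomal protein, 0.102 for potassium channel, 0.147 for proliferation and 0.297 for glutamate receptor genes. Without WT replicate 6 the ribosomal protein score lay -0.13 from WT (95% interval -0.253 to -0.016, exact permutation p = 0.0325). The calls of the complement and erythroid lists ended without WT replicate 6 (adjusted p = 0.427 and 0.273), that of cilia genes without Dp16 replicate 2 (0.193), of GABAergic genes without Dp16 replicate 2 (0.0838), of glutamate receptor genes without WT replicate 1 (0.192) and of proliferation genes without WT replicate 4 (0.055).

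In Dp16_2xIFNRs cortex the receptor genes were near their WT level while the rest of the segment stayed up. Ifngr2 stood at 41.8 ± 3.03 CPM, Ifnar1 at 45.7 ± 1.08, Ifnar2 at 14.7 ± 0.715 and Il10rb at 6.50 ± 0.333 (SD, n = 6), with adjusted p of 0.698, 0.805, 0.991 and 0.918 against WT. The receptor median differed from WT by 0.02 on the log2 scale (95% interval -0.09 to 0.13, exact permutation p = 0.615). Of the 111 other segment genes, 63 were called higher and none lower, 85 were called higher adjusted over the list alone, and the median fold was 1.47. App reached 2850 ± 97.2 CPM (adjusted p = 7.69e-07), Dyrk1a 132 ± 5.65 CPM (adjusted p = 5.77e-07) and Kcnj6 35.5 ± 2.91 CPM (adjusted p = 0.00163). All 12 neighbours of the receptor cluster lay above WT, 9 of them called. Olig1 was called at 1.26-fold (adjusted p = 0.0495), a call that ended without any of 14 libraries, at up to 0.11 without Dp16_2xIFNRs replicate 6.

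**Figure D3:**
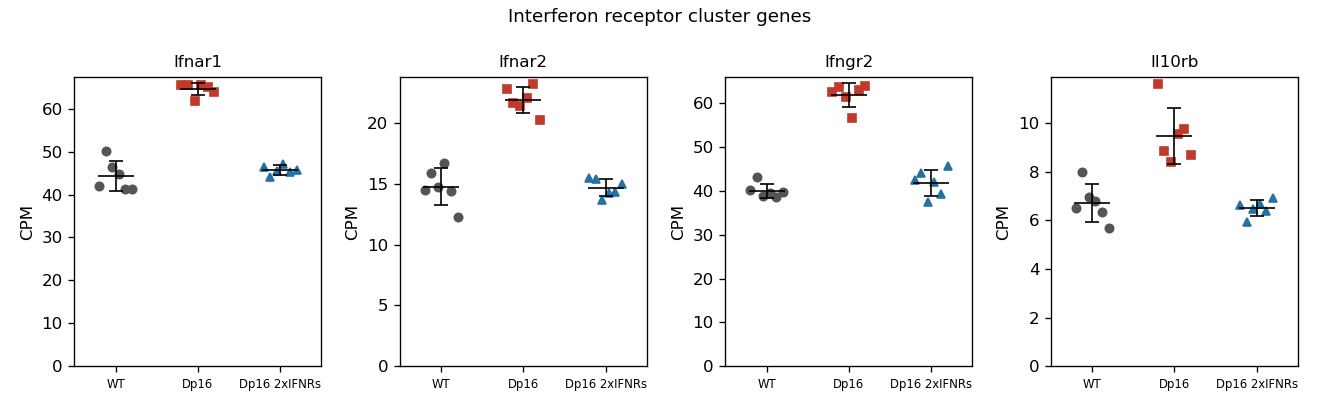
CPM of Ifnar1, Ifnar2, Ifngr2 and Il10rb (y axes, from 0) in each library of the 3 genotypes (x axes). Points are single libraries and bars give the mean and SD of 6 libraries. For Ifngr2 the means are 40 CPM in WT, 61.9 in Dp16 and 41.8 in Dp16_2xIFNRs.

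Outside the segment, 75 genes rose and 58 fell in Dp16_2xIFNRs. Sycp3 rose 4.27-fold (adjusted p = 0.000907), Selenov 3.41-fold (adjusted p = 5.99e-06) and Rnf17 2.22-fold (adjusted p = 0.00403). The linker histone gene H1f4 rose 2.58-fold (adjusted p = 0.0112), Bst1 2.43-fold (adjusted p = 0.02), the complement gene C3 2.41-fold (adjusted p = 0.0284), Lilra5 2.11-fold (adjusted p = 0.0464), the connexin gene Gja5 2.00-fold (adjusted p = 0.00176) and Exoc3l4 1.97-fold (adjusted p = 0.00277). Tbx1 fell to 0.341-fold (adjusted p = 0.00727), Rec8 to 0.483-fold (adjusted p = 0.0128), Gli1 to 0.534-fold (adjusted p = 0.00159) and Cbs to 0.589-fold (18.5 ± 2.63 CPM, adjusted p = 4.36e-05). Mfge8, which encodes a secreted glycoprotein, fell from 229 ± 32.1 to 155 ± 15.3 CPM (adjusted p = 0.00243). Egfl6 (0.636-fold), Mir7666 (0.641), Myo18b (0.648), Tcap (0.653) and Ighg2c (0.680) fell too.

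Several of these calls depended on single libraries. Without Dp16_2xIFNRs replicate 2 the adjusted p was 0.103 for C3, 0.107 for Egfl6, 0.115 for Mir7666 and 0.0648 for Ighg2c, and the highest values of the others were 0.0589 for Bst1 (WT replicate 3), 0.124 for Lilra5 (Dp16_2xIFNRs replicate 4), 0.0839 for Myo18b (Dp16_2xIFNRs replicate 5) and 0.0774 for Tcap (WT replicate 2). The outside count of 133 became 206 without WT replicate 6, with 70 higher and 136 lower, and also 206 when Dp16 replicate 3 was left out with it. It became 67, 87 and 88 without WT replicates 2, 3 and 4, and 63, 73, 79 and 81 without Dp16_2xIFNRs replicates 2, 3, 4 and 5.

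Interferon-stimulated genes stayed above WT in Dp16_2xIFNRs, set against the same 6 WT libraries as Dp16, so the 2 comparisons are not independent. In the type I list 45 of 46 members lay above WT, 2 were called and 15 were called adjusted over the list alone (adjusted p = 8.57e-14, and adjusted p = 0.147 with an estimated correlation). Lgals3bp rose 1.5-fold (adjusted p = 0.00727) and Ifi27 1.24-fold (adjusted p = 0.0313). The score was 0.31 above WT (95% interval 0.09 to 0.53, exact permutation p = 0.0108), with 6 of 6 libraries above the WT mean. Without WT replicate 6 the type I difference was 0.244 (95% interval 0.045 to 0.438, exact permutation p = 0.0216). WT replicate 4, at 0.275, lay within the Dp16_2xIFNRs range of 0.106 to 0.534. In the interferon gamma and antigen presentation list 28 of 33 lay above WT, 3 were called and 15 were called adjusted over the list alone (adjusted p = 1.5e-11, and adjusted p = 0.32 with an estimated correlation), and its score was 0.336 above WT (95% interval 0.067 to 0.617, exact permutation p = 0.0195). Without WT replicate 6 the interferon gamma difference was 0.234 (95% interval 0.032 to 0.414, exact permutation p = 0.0346). H2-D1 rose 1.33-fold (adjusted p = 0.00387), H2-K1 1.40-fold (adjusted p = 0.0194) and B2m, the light chain of class I molecules, 1.23-fold (adjusted p = 0.0399). The adjusted p reached 0.0844 for Ifi27 and 0.104 for B2m without Dp16_2xIFNRs replicate 6, and 0.056 for H2-K1 without WT replicate 2. With the replicate block the call of B2m ended too. Camera called the microglia list lower, with 5 of 20 members above WT and 0 called (adjusted p = 0.00943, and adjusted p = 0.763 with an estimated correlation), a call that ended without Dp16_2xIFNRs replicate 4 (0.0936). Its score differed from WT by -0.098 (95% interval -0.264 to 0.123, exact permutation p = 0.357), and by -0.186 without WT replicate 6 (95% interval -0.286 to -0.083, exact permutation p = 0.00649). The white blood cell score, whose list camera did not call, was 0.295 above WT (95% interval 0.092 to 0.54, exact permutation p = 0.00649), and 0.278 in Dp16 (95% interval -0.059 to 0.62, exact permutation p = 0.104).

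**Figure D4:**
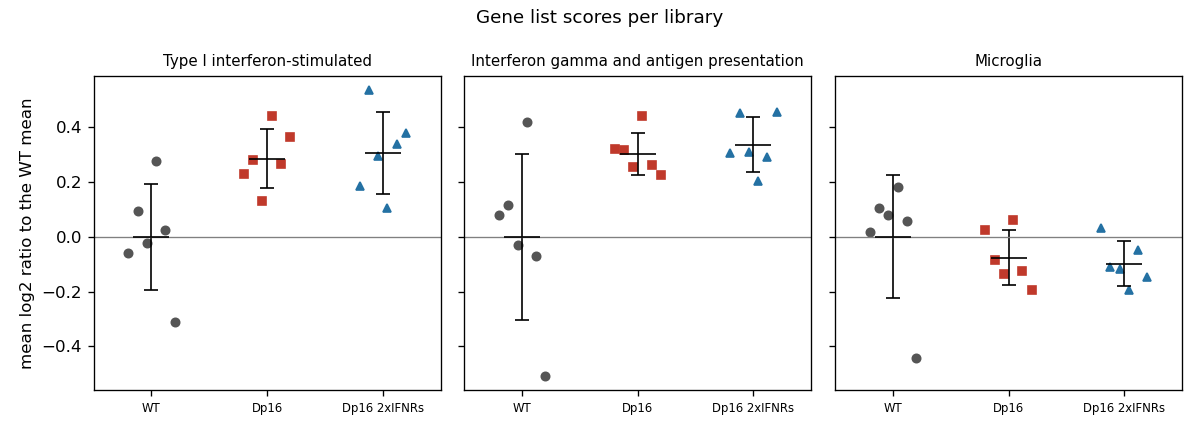
Mean log2 ratio to the WT mean (y axis) over the type I interferon-stimulated, interferon gamma and antigen presentation, and microglia lists in each library of the 3 genotypes (x axes). Points are single libraries and bars give the mean and SD of 6 libraries. All 12 duplication libraries lie above 0 in both interferon lists. WT replicate 4 lies within their range, at 0.275 and 0.417. WT replicate 6 stands at -0.44 in the microglia list.

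Camera called myelin genes higher in Dp16_2xIFNRs, with 20 of 20 members above WT and a median of 0.12 (adjusted p = 7.85e-07, and adjusted p = 0.468 with an estimated correlation). Mal, a myelin proteolipid gene, rose 1.46-fold (adjusted p = 0.00397), and 4 members were called adjusted over the list alone. Genes of the unfolded protein and integrated stress responses were called higher, with 20 of 24 above WT (adjusted p = 0.000208, and adjusted p = 0.32 with an estimated correlation), Mthfd2 at 1.47-fold (adjusted p = 0.0328) and 2 called adjusted over the list alone. Reactive astrocyte genes (15 of 17 above WT, adjusted p = 5.6e-05, and adjusted p = 0.32 with an estimated correlation), complement genes (10 of 15, adjusted p = 0.0214, and adjusted p = 0.611 with an estimated correlation), cilia genes (13 of 13, adjusted p = 0.00499, and adjusted p = 0.58 with an estimated correlation) and meningeal fibroblast genes (15 of 19, adjusted p = 0.0191, and adjusted p = 0.763 with an estimated correlation) were called higher, with 0 called members in the reactive astrocyte, cilia and meningeal lists. Adjusted over the list alone, 3 reactive astrocyte genes were higher. C4b rose 1.51-fold (adjusted p = 0.0405), Lyz2 1.53-fold (adjusted p = 0.00153), Cort 1.60-fold (adjusted p = 0.00207) and Dlx6os1 1.27-fold (adjusted p = 0.0302). Lower were the lists of ribosomal protein genes (0 of 38 above WT, adjusted p = 3.36e-14, and adjusted p = 0.468 with an estimated correlation), proliferation genes (3 of 19, adjusted p = 0.00106, and adjusted p = 0.147 with an estimated correlation), potassium channel genes (6 of 23, adjusted p = 0.0156, and adjusted p = 0.58 with an estimated correlation) and glutamate receptor genes (6 of 26, adjusted p = 0.00679, and adjusted p = 0.338 with an estimated correlation). Kcnj16 (0.766-fold, adjusted p = 0.00901), Sox4 (0.791-fold, adjusted p = 0.022) and the astrocyte gene Fgfr3 (0.810-fold, adjusted p = 0.0464) fell. Among the scores of these lists, exact permutation p against WT was 0.013 for myelin, 0.00866 for stress response, 0.00216 for reactive astrocyte, 0.0195 for complement and 0.0325 for proliferation genes. It was 0.0714 for cilia, 0.673 for meningeal fibroblast, 0.0649 for ribosomal protein, 0.0974 for potassium channel and 0.154 for glutamate receptor genes, whose intervals included 0. Without WT replicate 6 it was 0.00649 for ribosomal protein genes. Single libraries ended the list calls of complement (0.336 without WT replicate 6), meninges (0.943 without WT replicate 6) and potassium channels (0.111 without WT replicate 1). They also ended those of C4b (0.104), Mthfd2 (0.0915), Dlx6os1 (0.0902) and Sox4 (0.069) without Dp16_2xIFNRs replicate 2 and of Fgfr3 (0.133) without Dp16_2xIFNRs replicate 5.

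Set directly against Dp16, Dp16_2xIFNRs cortex differed in the receptor genes. Ifngr2 fell to 0.676-fold (log2 fold change -0.57, SE 0.0491, adjusted p = 5.2e-06), Ifnar1 to 0.708-fold (-0.50, SE 0.0447, adjusted p = 5.2e-06), Ifnar2 to 0.671-fold (-0.58, SE 0.0627, adjusted p = 9.06e-05) and Il10rb to 0.686-fold (-0.54, SE 0.0866, adjusted p = 0.0194). The call of Il10rb ended without any of 8 libraries, at up to 0.0835 without Dp16_2xIFNRs replicate 2. The other 111 segment genes had a median of -0.00, and their per-library medians differed by -0.01 (95% interval -0.04 to 0.01, exact permutation p = 0.238). Outside the segment edgeR called 0 genes, with 404 at an unadjusted p below 0.05 where 930 would be expected by chance, and DESeq2 and limma-voom also called 0. The cause of that shortfall was not examined, and it is no further evidence that no gene changed. The outside genes of smallest p were Msl3 (1.12-fold), Pigg (1.12), Nkx6-1 (1.76), Zfp874a (1.15) and Wdyhv1 (1.12) above Dp16, and Cd101 (0.557), Fancc (0.854), Pbx4 (0.849), Cacna1s (0.641) and Trim62 (0.897) below it, each with an adjusted p of 1.

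The type I interferon-stimulated score differed between the duplication genotypes by 0.02 (95% interval -0.15 to 0.19, exact permutation p = 0.779), and the interferon gamma score by 0.03 (95% interval -0.08 to 0.14, exact permutation p = 0.522). In these lists 30 of 46 and 22 of 33 members lay above Dp16, with 0 called either way by edgeR, also adjusted over the list alone. Besides the receptor list camera called 7 lists, none of which held a called member. Myelin genes (18 of 20 above Dp16, adjusted p = 2.54e-07, and adjusted p = 0.739 with an estimated correlation), stress response genes (19 of 24, adjusted p = 0.000312, and adjusted p = 0.739 with an estimated correlation), heat shock genes (13 of 14, adjusted p = 0.00354, and adjusted p = 0.739 with an estimated correlation) and protocadherin beta genes (20 of 21, adjusted p = 0.0059, and adjusted p = 0.91 with an estimated correlation) were called higher in Dp16_2xIFNRs. Ribosomal protein genes (1 of 38 above Dp16, adjusted p = 0.000312, and adjusted p = 0.944 with an estimated correlation), thalamus and hypothalamus genes (5 of 13, adjusted p = 0.0149, and adjusted p = 0.739 with an estimated correlation) and choroid plexus genes (0 of 14, adjusted p = 0.00353, and adjusted p = 0.91 with an estimated correlation) were called lower. The score intervals of all 7 included 0, with exact permutation p of 0.175 for myelin, 0.11 for stress response, 0.13 for heat shock, 0.234 for protocadherin beta, 0.392 for ribosomal protein, 0.0693 for thalamus and hypothalamus and 0.225 for choroid plexus genes. The choroid plexus call ended without Dp16 replicate 3 (adjusted p = 0.896), whose score was 2.1, the ribosomal call without Dp16 replicate 1 (0.4), the protocadherin call without Dp16 replicate 4 (0.209), the thalamus call without Dp16_2xIFNRs replicate 5 (0.0761) and the heat shock call without Dp16_2xIFNRs replicate 2 (0.0606).

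Both duplication genotypes shared 46 calls outside the segment, 35 higher and 11 lower, with 0 in opposite directions. Shared genes include a, Sycp3, Selenov, Rnf17, Bst1, Tbx1, Rec8, Gli1, Cbs, Lgals3bp, Ifi27, H2-D1, H2-K1, Lyz2 and Cort. Independent lists of these sizes would share 0.27 genes, a value that leaves out the shared WT libraries. In 10 simulations all 3 groups were redrawn as unchanged, WT included. Each simulated duplication group had at most 1 call outside the segment, too few to give an overlap for comparison. Across the 18602 outside genes, which are not independent replicates, the log2 fold changes against WT correlated at r = 0.677 with a covariance of 0.0334. Simulated unchanged groups gave r = 0.504 and a covariance of 0.0176, so that the covariance exceeded the simulated one by 0.0158. The simulation drew each gene independently, so it leaves out shifts of many genes in single WT libraries. It therefore cannot tell whether genotype accounts for the excess. With WT split into groups of 3 libraries, r averaged 0.208 over 20 assignments, from 0.096 to 0.322, with a covariance of 0.0143. In genes with a mean log2 CPM of 3 or more, r under this split averaged 0.181, from -0.111 to 0.524.

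Between sexes 12 genes differed, all on the X or Y chromosome. Ddx3y, Kdm5d, Uty, Eif2s3y and Gm29650 of the Y chromosome were higher in males and Xist (adjusted p = 2.29e-11), Eif2s3x (0.703-fold), Kdm5c (0.813-fold), 5530601H04Rik (0.762-fold) and Ddx3x (0.816-fold) lower, and all 18 libraries matched the labelled sex. For the interaction of sex with genotype edgeR called 0 genes in Dp16 vs WT (577 at an unadjusted p below 0.05), 0 in Dp16_2xIFNRs vs WT (1098) and 0 in Dp16_2xIFNRs vs Dp16 (350). DESeq2 called 0, 2 and 1, and limma-voom 0 in each. The leading genes were Sp3os (adjusted p = 1), Gpt (adjusted p = 0.826) and Cbs (adjusted p = 1).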

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

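The tests of the 3 patterns below were chosen after the values were seen, except the test of GC content and gene length, and so were the counts over other splits of the libraries for both comparisons with WT. The splits for Dp16_2xIFNRs vs Dp16, for sex and for the interactions were set before their results were read.

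Within each genotype, a library was singled out when its gap to the nearest of the other 5, divided by the range of the group, exceeded Dixon's 95% critical value, which chance gives in about 1 in 20 groups. Of 141 groups of list scores 10 did so, where 7 would by chance, and of 219 groups of named genes 14 did, where 10.9 would. WT replicate 6 accounted for 9 of these 24 cases. It was lowest in the scores for meningeal fibroblasts (gap ratio 0.81), microglia (0.737), activated microglia (0.735), endothelium (0.717) and cytokines with NF-kB targets (0.661). It was also lowest in Lyz2 (0.752), Kcnj16 (0.635) and Sox4 (0.63), and highest in Dnajc28 (0.697).

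Among the other scores, choroid plexus stood out in Dp16 replicate 3, at 2.1 against a mean of -0.07 in the other 5 (gap ratio 0.769), and myelin was highest in Dp16 replicate 1 (0.653). GABA and glycine receptors were lowest in Dp16 replicate 4 (0.664), immediate early genes in Dp16_2xIFNRs replicate 5 (0.648) and protocadherin beta genes in Dp16_2xIFNRs replicate 6 (0.698). Among genes, Lcn2 was highest in WT replicate 5 (0.853), Wrb in WT replicate 3 (0.819), Mfge8 in Dp16_2xIFNRs replicate 1 (0.71), Tcap in Dp16 replicate 2 (0.692), and Mir7666 (0.666) and Egfl6 (0.655) in Dp16_2xIFNRs replicate 5. Lowest were Ighg2c in WT replicate 5 (0.742), Cct8 (0.71) and Ifngr2 (0.665) in Dp16 replicate 4 and H1f4 in Dp16 replicate 2 (0.641).

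The low marker scores of WT replicate 6 also covered astrocytes, pericytes, oligodendrocyte precursors, myelin and GABAergic neurons, each below all 17 other libraries, while its glutamatergic neuron score was 0.08. A lower share of all non-neuronal cells alike would lower these markers together, but the microglia score less the myelin score lay -4.32 SD of the other 5 WT libraries from their mean. After a correction for GC content and gene length the gap ratio of the microglia score was 0.743, against 0.738 before, so these biases did not account for it. A difference in how the tissue was taken, or in this animal, may remain, and no biological explanation was tested.

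The nonagouti gene stood above WT in all 12 duplication libraries, with the lowest of them 25 times the highest WT value. A change of the whole surrounding region was tested by its neighbours, of which 0 of 36 tested within 1 Mb were called by edgeR (smallest adjusted p = 0.199 in Dp16 and 0.145 in Dp16_2xIFNRs). Skin or hair tissue would bring keratin transcripts, but the summed CPM of 12 skin markers differed by -0.915 from WT (95% interval -2.89 to 1.09, exact permutation p = 0.343), against a rise of 1.35 CPM of the gene. That test replaced an earlier one that compared levels and decided nothing, since cortex of all genotypes held Krt10 (5.73 CPM) and 3 other markers above 1 CPM. A candidate explanation is coat colour marker sequence carried with the engineered chromosome, which cannot be told apart from an effect of the duplication because both duplication genotypes would carry it.

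The type I interferon-stimulated list was above WT in both duplication genotypes. Receptor gene dosage as the whole cause would return the score to WT in Dp16_2xIFNRs, where it stayed 0.306 above WT (95% interval 0.09 to 0.525, exact permutation p = 0.0108). Without WT replicate 6, Dp16 remained 0.222 above WT (95% interval 0.056 to 0.378, exact permutation p = 0.0195). The microglia score did not rise in Dp16 (difference from WT -0.076, 95% interval -0.255 to 0.155, exact permutation p = 0.504), which argues against more microglia as the whole cause. The type I score less the microglia score was 0.36 higher in Dp16 (95% interval 0.221 to 0.503, exact permutation p = 0.00216). Subtracting a score that was lower in Dp16 raises the difference by itself, so this adds no separate support. The score less the white blood cell score differed by 0.006 in Dp16 (95% interval -0.256 to 0.267, exact permutation p = 0.959). More white blood cells, or more of other cells that carry genes of that list, were therefore not excluded. An effect of other segment genes may also account for it and stays untested.

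Other splits of the libraries, 100 per result, bear on chance. For Dp16 vs WT 1 split, the real one, gave as many calls as 140 (highest other 86), and 2 gave as many as 72 outside the segment (86). For Dp16_2xIFNRs vs WT 1 gave as many as 196 (7) and 1 as many as 133 outside (7), and for Dp16_2xIFNRs vs Dp16 1 gave as many as 4 (1). Another split exceeded the 72 outside calls, so chance is not excluded for that count. For the 133 outside calls, no other split among the 100 drawn of 462 possible gave more than 7. The counts of 140, 196 and 4 include 68, 63 and 4 segment genes, whose copy number differs by design, so they decide little. Nor is chance excluded for the numbers of lists called, since 71 splits gave as many as 14 (highest other 27), 48 as many as 15 (25) and 87 as many as 8 (24). For sex, 2 splits gave as many as 12 calls, the other with 300. Of the 0 outside calls in Dp16_2xIFNRs vs Dp16 (404 at an unadjusted p below 0.05 by edgeR; DESeq2 and limma-voom 0) and the 0 calls for the interactions (577, 1098 and 350; DESeq2 0, 2 and 1), the splits say nothing about chance, since all 100 reach 0 by construction. The highest counts of other splits were 1 for the outside calls and 277, 1 and 1 for the interactions. What set apart the splits with 300 and 277 calls was not examined.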

How the results depend on the processing

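The fit without WT replicate 6 and Dp16 replicate 3 and the one with choroid plexus and striatum scores were chosen after seeing the data. Of 595 alternatives to 19 main results, 539 were rated the same, 34 weaker, 17 stronger, 5 moved and 0 reversed. Counts within a factor of 1.5 of the main count were rated the same, as were medians within the SD between libraries. Of 13774 alternatives to 384 results of named genes, 13138 kept their status as called or not called, 566 were weaker and 70 stronger. Only 54, 56 and 4 of these results were calls, in Dp16 vs WT, Dp16_2xIFNRs vs WT and Dp16_2xIFNRs vs Dp16. Leaving out single libraries ended 13 of the 28 named calls outside the segment in Dp16 vs WT and 16 of 34 in Dp16_2xIFNRs vs WT. Of 999 alternatives for called lists 864 were kept and 135 weaker. Calls in Dp16 vs WT numbered 140, and 250 with DESeq2, 51 in males, 42 in females and 88 at a threshold of 0.01. Outside the segment the 72 became 180 with DESeq2, 37 from only the 12 libraries compared, 12 in males, 4 in females, 44 without WT replicate 6 and Dp16 replicate 3, 27 at 0.01 and 133 at 0.1. The 196 calls in Dp16_2xIFNRs vs WT became 405 with DESeq2, 41 in males, 74 in females, 94 at 0.01 and 307 at 0.1. Outside the segment the 133 became 338 with DESeq2, 214 with quality weights and 209 with a term for a single series of sample identifiers against the rest. It became 209 with identifiers as a random block, 8 in males and 31 in females. It was 206 without WT replicate 6 and Dp16 replicate 3, 37 at 0.01 and 241 at 0.1. The 4 calls in Dp16_2xIFNRs vs Dp16 became 0 in males and 0 in females by edgeR, with 4 by DESeq2 and limma-voom in all libraries. Fits of a single sex hold fewer samples, and elsewhere the cause was not tested.

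Leaving out each library gave 121 to 270 calls in Dp16_2xIFNRs vs WT, 63 to 206 outside the segment, 38 to 79 outside in Dp16 vs WT, and a segment median of 0.545 to 0.574 in Dp16_2xIFNRs. Without a filter the Dp16 segment median was 0.566. Lists called fell from 14 to 3 with an estimated correlation and 4 with fry, from 15 to 2 and 4, and in Dp16_2xIFNRs vs Dp16 from 8 to 1 and 1, and to 5 with choroid plexus and striatum scores. DESeq2 called 21 genes for sex and 2 and 1 for the interactions with Dp16_2xIFNRs. The correlation between genotypes of 0.677 was 0.707 in well-expressed genes and 0.208 with WT split.

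The labels do not say that a shared number pairs libraries, although some of these libraries also share a sample identifier, sex and age. The median correlation of their deviations was 0.108 over 18 pairs, 11 of them over 0.1, and 6 of 18 libraries were closest to their own number. Over the 90 pairs with different numbers the median was -0.032, with 22 over 0.1. Over the 7 pairs with the same identifier it was 0.174, with 5 over 0.1. With the replicate block there were 304 calls in Dp16_2xIFNRs vs WT, 237 outside the segment, a correlation of 0.699, and by edgeR an adjusted p of 0.0812 for Il10rb in Dp16_2xIFNRs vs Dp16. In Dp16 vs WT the block gave 0.0513 for H2-D1, 0.0524 for H2-DMa, 0.0619 for Bst2 and 0.0976 for H2-K1, and in Dp16_2xIFNRs vs WT 0.0503 for Mir7666, 0.055 for B2m and 0.0613 for C4b. Depth limits genes of low counts, such as Sycp3 and Cd300lg.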

Other observations

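The test across chromosomes was chosen after the list of called genes was seen. Lists of neighbouring brain regions and other cell types that camera did not call against WT are given with adjusted p for Dp16 and for Dp16_2xIFNRs. Striatum genes stood at 0.361 and 0.699, hippocampus genes at 0.591 and 0.704, olfactory bulb genes at 0.406 and 0.948, thalamus and hypothalamus genes at 0.349 and 0.504 and choroid plexus genes at 0.105 and 0.704. Astrocyte genes stood at 0.591 and 0.248, oligodendrocyte precursor genes at 0.361 and 0.253, glutamatergic neuron genes at 0.176 and 0.16, endothelial genes at 0.234 and 0.69, pericyte genes at 0.229 and 0.511, activated microglia genes at 0.155 and 0.15 and white blood cell genes at 0.0781 and 0.0542.

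Among pathway lists, cytokine and NF-kB target genes (12 of 19 tested) stood at adjusted p of 0.0745 and 0.0753. Interferon signalling kinases stood at 0.229 and 0.211, immediate early genes at 0.105 and 0.902 and glucocorticoid and circadian genes at 0.914 and 0.704. Presynaptic genes stood at 0.264 and 0.16, GABA and glycine receptors at 0.0781 and 0.112 and protocadherin beta genes at 0.407 and 0.33. Oxidative phosphorylation genes stood at 0.487 and 0.699, mitochondrially encoded genes at 0.438 and 0.902, cholesterol synthesis genes at 0.914 and 0.948 and NRF2 target genes at 0.277 and 0.123. Heat shock genes stood at 0.722 and 0.122 and senescence genes at 0.722 and 0.69. Genes of amyloid and tau handling, with 4 segment members left out, stood at 0.591 and 0.565. Orthologues of human chromosome 21 genes that lie on mouse chromosomes 10 and 17, outside the segment, stood at 0.591 and 0.704, with 23 of 45 above WT in both genotypes and Cbs the 1 called gene.

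The scores of some of these lists passed the test between libraries, whose p was not adjusted over lists. The score of cytokine and NF-kB target genes was 0.249 above WT in Dp16 (95% interval 0.102 to 0.407, exact permutation p = 0.00866) and 0.294 in Dp16_2xIFNRs (95% interval 0.146 to 0.449, exact permutation p = 0.00649). In Dp16_2xIFNRs the activated microglia score was 0.158 above WT (95% interval 0.018 to 0.346, exact permutation p = 0.0238). The GABAergic neuron list, not called there (adjusted p = 0.18), had a score 0.063 above WT (95% interval 0.021 to 0.108, exact permutation p = 0.0173). Without WT replicate 6 the scores of cytokine and NF-kB target genes were 0.2 and 0.245 above WT (exact permutation p = 0.0108 and 0.00866). In Dp16_2xIFNRs the white blood cell score was then 0.204 above WT (exact permutation p = 0.013), the activated microglia score 0.082 (95% interval 0.001 to 0.158, exact permutation p = 0.0498) and the GABAergic neuron score 0.054 (exact permutation p = 0.0303). The astrocyte score then differed from WT by -0.13 (95% interval -0.254 to -0.01, exact permutation p = 0.0411) and the oligodendrocyte precursor score by -0.115 (95% interval -0.232 to -0.004, exact permutation p = 0.0411), where with all libraries both intervals included 0 (exact permutation p = 0.55 and 0.333).

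No chromosome passed the test for a higher or lower share of outside calls, with smallest adjusted p of 0.78 in Dp16 and 0.48 in Dp16_2xIFNRs by Fisher's exact test. That test counts genes and does not measure the spread between samples.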
